A study of Mus musculus with 24 samples.

How the data were processed

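Histone H3 acetylated at lysine 9 (H3K9ac), a mark found mostly at active promoters, was mapped by chromatin immunoprecipitation and sequencing in day 5 embryoid bodies, the cell aggregates that mouse embryonic stem cells form when they differentiate. Gcn5, encoded by Kat2a, is a histone acetyltransferase that can acetylate this residue. Per the labels, 2 clones carried the floxed Gcn5 allele in homozygous form (fx/fx, clones 4_1 and 6_1) and 2 lacked Gcn5 (null, clones 4_C2 and 6_C4), with 2 replicates of each clone. Clones 4_1 and 4_C2 form isolate pair 4, and clones 6_1 and 6_C4 form isolate pair 6. The series holds 24 samples, of which the 8 H3K9ac libraries were analysed here and the 16 samples of total H3 and input DNA were not used here. Per the labels' protocols, libraries were sequenced as single reads on a HiSeq3000.

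The authors deposited a peak list for each H3K9ac library, not one list for pooled replicates. Each deposited list holds the chromosome, start and end of every peak, and no height, score, fold enrichment or p-value. Bowtie 1.1.2, MACS 1.4.2 and the mm10 build are named per the submitters' processing notes. The peak calling threshold, the control library and any filters are not given in the sources used here. The depth of each library is unknown, so no counting interval could be given, and a deeper library can yield more and wider peaks from the same chromatin. Widths and overlaps of called peaks were therefore the only measurements, and acetylation strength inside a peak was not measured.

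Peak coordinates are given on mm10, counted from 1. The gene table used was that of assembly GRCm38.p6, whose primary sequence is that of mm10. It gives gene spans without strand, exons or untranslated regions, so transcription start sites could not be taken from it. The planned promoter windows were replaced by windows of 1000 bp either side of both annotated ends of each of 21887 protein-coding genes, called gene ends here. A left end is the one with the lower coordinate. On average 54.8% of genes had a peak at an end, against 7.95% after all genes were shifted by 1 Mb. Of the genes with a peak at an end in at least 1 library, 10954 had it at one end only and 2667 at both.

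Peaks of all libraries that overlapped by at least 1 bp were merged into 26034 regions, and a library had a region when any of its peaks overlapped it. A gene had a peak in a library when a peak overlapped either of its end windows. Peak number, covered length, median width and the share of peaks at gene ends were compared between 4 fx/fx and 4 null libraries with two-sided exact permutation tests over 70 splits, for which the smallest p is 0.0286. The design text calls the experiments independent without naming separate cultures, and the 2 replicates of a clone share its history, so p-values describe the spread between these libraries.

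Region width was the number of base pairs covered by peaks in a library, on the log2 scale and centred on each library's median. It was tested with limma 3.58.1 in R 4.3.3 over the 10171 regions present in all 8 lists, with isolate pair as a covariate and Benjamini-Hochberg adjustment at 0.05. A second fit tested whether the genotype effect differed between the isolate pairs. Gene lists with at least 5 genes whose region was tested were compared with all other such genes by limma's camera with a preset correlation of 0.01. Regions away from gene ends did not enter, and a region shared by neighbouring genes was entered for each of them. A gene's region was the one at its ends with the largest covered length. Overlaps were tested with Fisher's exact test, two-sided. Enrichment of lists among genes used as background the genes with a peak in at least 1 of the libraries compared. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

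Before the data were examined, 22 gene lists (717 entries, of which 715 matched the gene table), 13 single genes and the rule for naming others were fixed. The rule took up to 10 genes per direction with a peak in all libraries of one genotype and none of the other, up to 10 per direction past the limma threshold, and up to 4 members of each described list, chosen by the difference in libraries with a peak and then by width change. Genes named outside this rule are said to be so, and some genes that it takes are not reported here. The tests were tried on simulated data. With widths simulated for the comparison of null with fx/fx over 10171 regions, limma recovered 57 of 100 regions changed 1.5-fold and 90 of 100 changed 2-fold, with 6 false calls. All changed regions were simulated together, which eases the adjustment for multiple tests. The noise was independent between libraries and regions, without clone effects. These rates can therefore overstate what the real comparison would recover.

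The alternatives fixed beforehand were a replicate block, permutation within isolate pairs, no isolate pair term, clone means, uncentred widths, regions found in at least 4 lists with a pseudocount of 500 bp, merging across gaps of up to 1000 bp, a region counted only when 50% covered, windows of 500 and 2500 bp, camera with an estimated correlation, and leaving out each library in turn. Alternatives that filter or rank peaks by score could not be computed from lists without scores. Chosen after seeing the data were lists restricted to the 12041 widest peaks of each library, peaks of at least 1000 bp, removal of chromosomes 8 and 11, the 14841 genes whose windows touch no window of another gene, the pseudocount fit of the difference between pairs, a pseudocount alone, an estimated correlation with a pseudocount and regions in at least 4 lists, and leaving out a library with the differences averaged within pairs. All alternatives for the overlap of lost genes, its rearranged labels and the Kat2a edge were also chosen after seeing the data. Keeping the 12041 widest peaks drops more narrow peaks from longer lists. That raises their median width by construction, and fx/fx lists were longer on average.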

Results

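The data were 8 lists of H3K9ac peaks from day 5 embryoid bodies, 4 from Gcn5 fx/fx cells and 4 from Gcn5 null cells. The lists held between 12041 and 20809 peaks. Regions found in all 8 lists numbered 10171 of 26034, and 6679 regions were found in 1 list. The Jaccard index of 2 lists, the regions found in both over those found in either, had a median of 0.732 between replicates of the same clone. It was 0.747 between genotypes within an isolate pair and 0.661 between isolate pairs within a genotype. Sequencing depth is unknown for these lists.

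The first comparison concerned the deleted gene and the genes named in the study's question, which links Gcn5 to FGF signalling and c-Myc. Kat2a, which encodes Gcn5 (chromosome 11, 100704746 to 100712485), had a peak in 4 of 4 fx/fx and 4 of 4 null libraries. The peaks lay across its right end and the neighbouring small gene Hspb9. Covered length there was 3630 ± 269 bp in fx/fx and 3132 ± 127 bp in null libraries (SD, n = 4 each). After centring on each library's median, the log2 change was -0.08 ± 0.09 (SE) with a limma adjusted p of 0.869. The log2 changes of the other genes are centred in the same way. Which part of Kat2a was deleted is not given in the sources used here, so a peak at its end does not check the genotype. The paralogous acetyltransferase gene Kat2b likewise had a peak in all 8 libraries, with a log2 change of 0.11 ± 0.20 (SE, limma adjusted p = 0.924).

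Myc, which encodes the transcription factor c-Myc (chromosome 15, 61985341 to 61990361), had a peak in 4 of 4 fx/fx and 3 of 4 null libraries, the exception being replicate 2 of clone 4_C2, the shortest list. Covered length at Myc was 3812 ± 1246 bp in fx/fx and 2353 ± 2017 bp in null libraries (SD, n = 4 each). Mycn, its relative, had a peak in all 8 libraries, with a log2 change of -0.12 ± 0.09 (SE, limma adjusted p = 0.783). The ligand gene Fgf5, an epiblast marker, was covered in all 8 (log2 change 0.28 ± 0.14, SE, limma adjusted p = 0.724), as was the receptor gene Fgfr1 (-0.13 ± 0.11, limma adjusted p = 0.80). Fgf8 had a peak in 3 fx/fx and 4 null libraries, and Fgf4 in 3 of each. The ERK feedback inhibitor genes Spry2 and Dusp6 had peaks in all 8 libraries, with log2 changes of -0.08 ± 0.09 and -0.04 ± 0.12 (SE, limma adjusted p = 0.855 and 0.953). The pluripotency genes Pou5f1 and Nanog each had a peak in 4 fx/fx and 3 null libraries, and the mesoderm gene T in 2 of each. None of the genes tested by limma passed, and the difference in the number of libraries with a peak was at most 1 for each of the others.

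**Figure D1:**
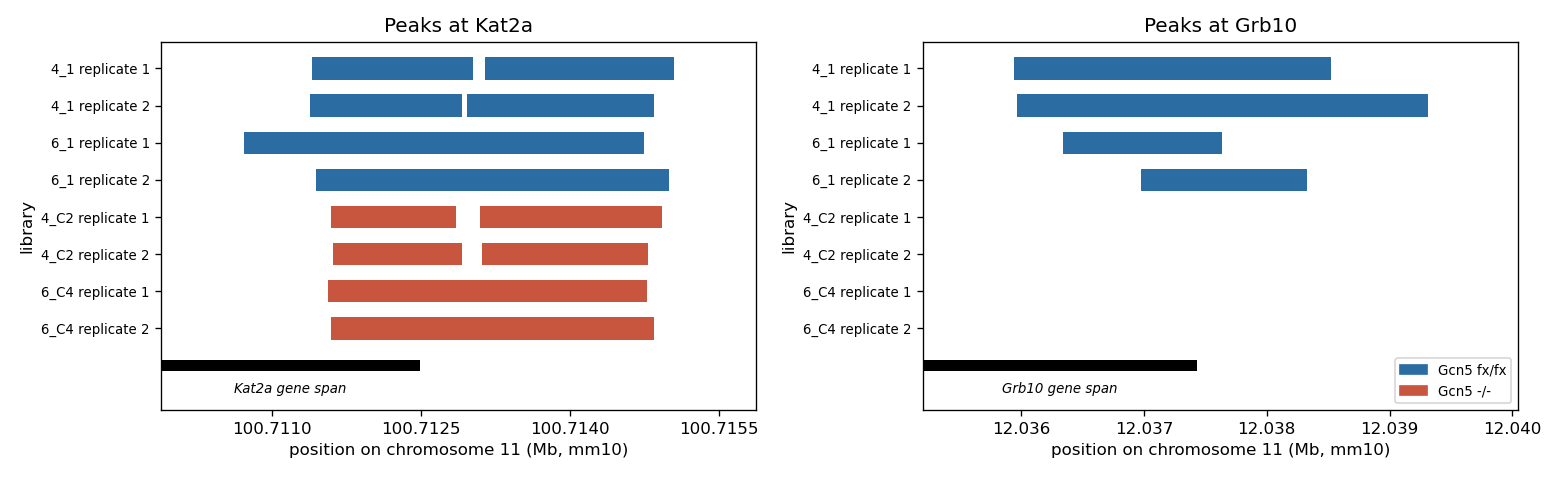
Called H3K9ac peaks at Kat2a and Grb10 in each library (bars, position on chromosome 11 of mm10 in Mb, blue for fx/fx and red for null), with the part of the gene span in view in black. All 8 libraries have a peak at Kat2a, and the 4 fx/fx but no null libraries have one at the right end of Grb10.

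The second comparison asked how the genome-wide distribution of H3K9ac differed upon Gcn5 loss. Null libraries held 15942 ± 3098 peaks and fx/fx libraries 16965 ± 3342 (SD, n = 4 each, exact permutation p = 0.629). Peaks covered 32.0 ± 7.78 Mb in null and 36.6 ± 8.90 Mb in fx/fx libraries (SD, n = 4 each, exact permutation p = 0.486). Median peak width was 1759 ± 81.9 bp in null and 1882 ± 118 bp in fx/fx libraries (SD, n = 4 each, exact permutation p = 0.0857). Without replicate 2 of 6_1 the difference in median width went from -122.8 to -64.6 bp (exact permutation p = 0.229). Genes with a peak at an end numbered 11747 ± 954 in null and 12249 ± 710 in fx/fx libraries (SD, n = 4 each, exact permutation p = 0.486). The share of peaks at gene ends was 68.8 ± 7.38% in null and 67.8 ± 8.39% in fx/fx libraries (SD, n = 4 each, exact permutation p = 0.83).

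Peak number, covered length, genes with an end peak and the gene-end share differed more between isolate pairs than between genotypes, and median peak width did not. Libraries of pair 6 held 19017 ± 1275 peaks and those of pair 4 held 13891 ± 1524 (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). Within pair 4 the mean was 14288 peaks in fx/fx and 13494 in null libraries, and within pair 6 it was 19643 and 18391. Covered length within pair 4 averaged 29.1 Mb in fx/fx and 26.0 Mb in null libraries, and within pair 6 it averaged 44.1 and 37.9 Mb. Without replicate 2 of clone 4_C2, the difference within pair 4 was 659.5 peaks and 1.09 Mb, both higher in the null clone. Without replicate 1 of clone 4_1 it was 234.0 peaks and -0.669 Mb. Averaged over the pairs, peak number stayed lower in null libraries without any one library, by a difference of -1750 to -296.5 peaks.

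**Figure D2:**
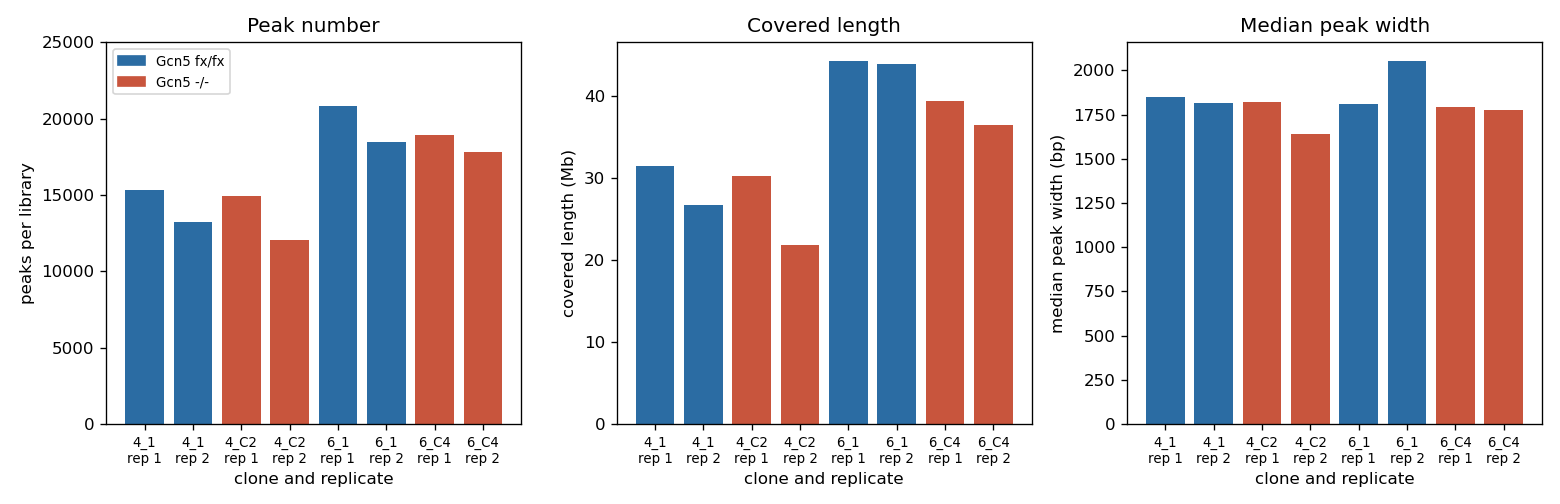
Number of peaks, covered length in Mb and median peak width in bp for each library (bars, blue for fx/fx and red for null, by clone and replicate). Peak numbers run from 12041 in replicate 2 of 4_C2 to 20809 in replicate 1 of 6_1, and all pair 6 libraries lie above all pair 4 libraries.

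Grb10, which encodes an adaptor protein that restrains growth factor receptor signalling, was among 10 genes with an end peak in 4 of 4 fx/fx and 0 of 4 null libraries. Others were Ackr3 (an atypical chemokine receptor), the cadherin genes Cdh7 and Pcdh17, Rtn1 (a neuronal reticulon), Rfx4 (a transcription factor of the neural tube), Hdac8 (a histone deacetylase), Tmsb4x (an actin-binding thymosin) and Tha1. No gene had the reverse pattern. The Grb10 region (chromosome 11, 12035939 to 12039310, at the gene's right end) was covered over 2145 ± 996 bp in fx/fx libraries (SD, n = 4). The Ackr3 region (chromosome 1, 90201822 to 90205896, at its left end) was covered over 2067 ± 931 bp, the Rtn1 region (chromosome 12, 72407529 to 72409344, right end) over 1424 ± 231 bp, and the Rfx4 region (chromosome 10, 84754651 to 84756797, left end) over 1334 ± 305 bp. The remaining genes named here were covered over 987 to 1376 bp on average. At Tmsb4x the null libraries kept a mean of 800 bp of peak in the same merged region, outside the gene's end windows.

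By region, 17 were present in 4 of 4 fx/fx and 0 of 4 null libraries and 0 the other way round. Without replicate 2 of 4_C2, 18 regions and 10 genes were in fx/fx libraries alone and 21 regions and 6 genes in null libraries alone. Of the 17, 11 lay at a gene end, 2 inside a gene away from its ends and 4 outside protein-coding genes. The inner regions were in Mpp2 (chromosome 11, 102059756 to 102062107) and Tiam1 (chromosome 16, 89959925 to 89961212), both named after their values were seen. Of the 35 splits of the 8 libraries into 4 and 4, 15 gave at least 17 regions and 9 gave at least 10 genes. The splits include that by isolate pair, with 741 regions and 137 genes.

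Clones were next compared within each isolate pair. In pair 4, 250 genes had an end peak in both fx/fx and neither null library, and 51 the reverse. Without replicate 2 of 4_C2, the shortest list, these counts were 329 and 329, and without replicate 1 of 4_C2 they were 1050 and 83. The 250 included 4 of 24 primitive streak and mesoderm genes against 0.473 expected (Fisher's exact p = 0.00114, adjusted p = 0.0252 over 22 lists), namely Tbx6, Hand2, Eomes and Gsc, all transcription factor genes of early mesoderm. They also included 3 of 18 genes of the Hox clusters, Hoxa2, Hoxa5 and Hoxa6 (Fisher's exact adjusted p = 0.0545). In pair 6, 153 genes were lost and 39 gained in the null clone, with 0 of 27 primitive streak and mesoderm genes and 0 of 22 Hox genes among those lost. The difference between the pairs was not tested for these lists. Leaving out 1 library loosens the criterion, and pair 6 then lost 287 to 444 genes. Without replicate 2 of 6_C4, 5 of 27 primitive streak and mesoderm genes were among those lost in pair 6 (Fisher's exact adjusted p = 0.00808) and 3 of 21 Hox genes (Fisher's exact adjusted p = 0.138). The enrichment in pair 4 was not called without replicate 1 of 4_C2 (Fisher's exact adjusted p = 0.242) or replicate 2 of 4_C2 (Fisher's exact adjusted p = 0.0694). Without replicate 2 of 4_1, when 689 genes were lost, other lists were called too, with 8 of 18 Hox genes (Fisher's exact adjusted p = 2.26e-05), 7 of 25 neuroectoderm genes (0.00210), 5 of 15 endoderm genes (0.00502), and epiblast and fibroblast genes (0.0437 each). The enrichment was then not particular to mesoderm.

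Regions lost in the null clone numbered 479 in pair 4 and 677 in pair 6, with 17 in common against 12.5 expected (ratio 1.36, Fisher's exact p = 0.190). Genes lost in both pairs numbered 10 against 2.81 expected (ratio 3.56, Fisher's exact p = 0.000523). That test takes every marked gene as equally open to loss. With the genotype labels rearranged within pairs, 12 of 36 arrangements, the real one included, gave a ratio as large and 3 a Fisher's exact p as small. For regions 17 of 36 gave a ratio as large. Regions gained numbered 153 and 215, with 0 in common against 1.26 expected (Fisher's exact p = 0.641). This ratio was 0.104 without replicate 2 of 6_C4 and 1.58 without replicate 2 of 4_C2, past the threshold in opposite directions. Of the 153, 45 (29.4%) lay on chromosome 11, which held 10.5% of all regions. Lost regions were narrow, with a median fx/fx width of 1239 bp in pair 4 against 2164 bp for regions kept, and 1296 against 2346 bp in pair 6. Without replicate 2 of 6_1 the overlap of lost regions fell to 0.387 of that expected (Fisher's exact p = 8.44e-09), and without replicate 1 of 6_C4 it was 1.97 times that expected (Fisher's exact p = 2.37e-07). It was thus past the threshold in either direction depending on the library left out. The ratio for genes ran from 1.35 without replicate 1 of 4_C2 to 4.64 without replicate 1 of 6_C4.

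Width was then compared in regions that all libraries shared. No region was narrower or wider in null libraries after adjustment with limma, where 327 regions had an unadjusted p under 0.05 for narrowing and 378 for widening. The median region of null libraries was narrower by a log2 change of -0.14 before centring (11.08 ± 0.19 against 11.22 ± 0.15, SD, n = 4 each, exact permutation p = 0.343). All log2 changes in width, above and below, are relative to that shift unless given as uncentred. Without centring, limma again called 0 regions, with 1296 narrower and 19 wider at an unadjusted p under 0.05. The region with the lowest p covered Hoxb2 (chromosome 11, 96351324 to 96355456, both gene ends), at 3468 bp in fx/fx and 1814 bp in null libraries, a log2 change of -0.81 ± 0.14 (SE, limma adjusted p = 0.625). It was singled out after its value was seen. Using regions in at least 4 lists with a pseudocount, limma called 16 narrower and 1 wider. With the pseudocount alone over regions in all lists it called 0, so these calls came with adding regions absent from some lists.

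Among the 16 gene lists with enough tested genes, 4 were narrower in null libraries than the regions of other genes by camera and 0 were wider. Compared by the median of each library instead, none of the 4 passed (exact permutation p of 0.571 for ribosomal proteins, 0.314 for pluripotency and for Myc targets, and 0.2 for Hox clusters). Unlike camera, that test took no account of the isolate pairs. The list with the lowest camera p, ribosomal protein genes, was fixed beforehand as a control list. All 76 of its genes had a peak in every library. Their median log2 change was -0.06, with 50 of 76 members below 0 (adjusted p = 0.00719, and adjusted p = 0.472 with an estimated correlation). The members with the largest changes were Rps24 (-0.62 ± 0.17, SE), Rpl37a (-0.47 ± 0.14), Rps10 (-0.34 ± 0.09) and Rpl12 (-0.32 ± 0.09), each with a limma adjusted p of 0.714. Naive and general pluripotency genes had a median of -0.18 with 12 of 13 members below 0 (adjusted p = 0.0101, and adjusted p = 0.404 with an estimated correlation). Myc targets had a median of -0.04 with 42 of 59 below 0 (adjusted p = 0.0101, and adjusted p = 0.404 with an estimated correlation). The 5 Hox cluster genes tested had a median of -0.47 with 4 of 5 below 0 (adjusted p = 0.0424, and adjusted p = 0.404 with an estimated correlation).

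The pluripotency list differed in sign between the pairs, with a median of -0.41 in pair 4 and 0.02 in pair 6, and was not called without replicate 2 of 4_1 or replicate 2 of 4_C2 (adjusted p up to 0.397). It was also not called with uncentred widths (adjusted p = 0.158), with equal-length lists by width (adjusted p = 0.311) or with no isolate pair term (adjusted p = 0.0544). Medians in pairs 4 and 6 were -0.07 and -0.04 for ribosomal proteins, -0.08 and -0.04 for Myc targets, and -0.41 and -0.53 for Hox clusters. Between same-numbered libraries of pairs 4 and 6, ribosomal medians were -0.11 and -0.08 for replicate 1, and -0.01 and 0.02 for replicate 2. Those of Hox clusters were -0.14 and -0.37 for replicate 1, and -0.76 and -0.09 for replicate 2. Ribosomal proteins and Myc targets were not called without replicate 2 of 4_1 or replicate 1 of 4_C2, each with an adjusted p up to 0.203. Hox clusters were not called without replicate 2 of 4_C2, replicate 1 of 6_1 or replicate 1 of 6_C4 (adjusted p up to 0.788), nor with uncentred widths (adjusted p = 0.475), with merging across gaps (adjusted p = 0.0544), with a pseudocount alone (adjusted p = 0.0602) or with a pseudocount and regions in at least 4 lists (adjusted p = 0.0546). Myc targets were not called over genes with windows of their own (adjusted p = 0.126). Leaving out each library in turn, the median ran from -0.26 to -0.10 for pluripotency, -0.09 to -0.02 for Myc targets and -0.07 to -0.03 for ribosomal proteins. For Hox clusters it ran from -0.82 to -0.07 over 7 of these settings, since without replicate 1 of 4_1 fewer than 5 of the genes could be tested. No member of these 4 lists passed over all regions, and adjusted over the list alone 1 did, Hoxb2 (limma adjusted p = 0.00101).

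**Figure D3:**
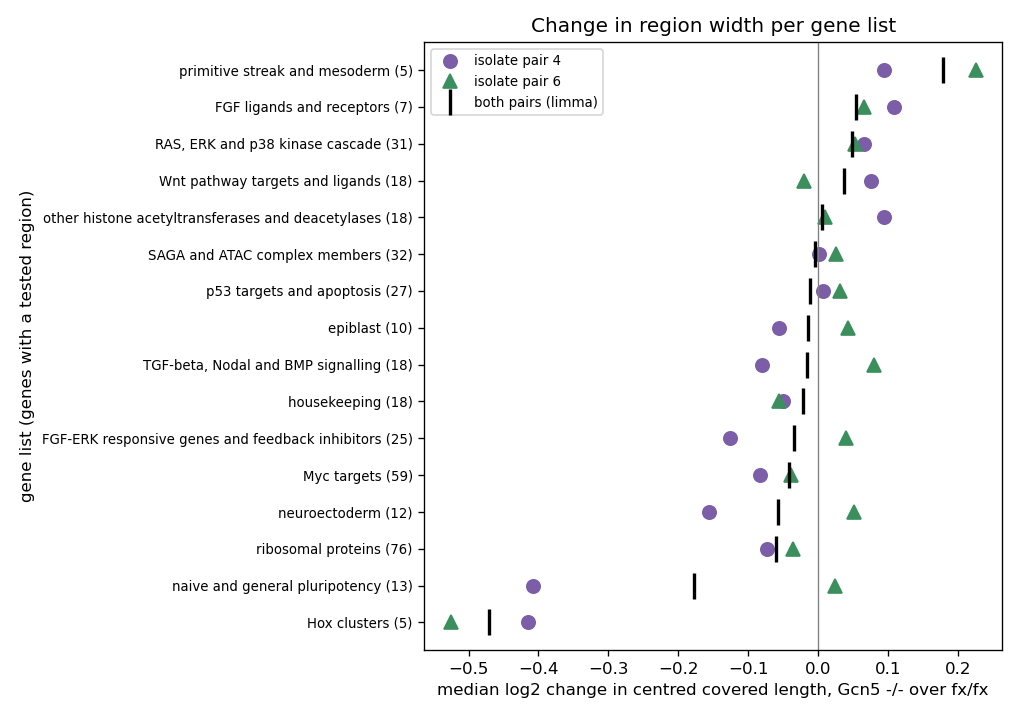
Median log2 change in centred covered length, null over fx/fx, for each gene list with its number of tested genes (circles for isolate pair 4, triangles for pair 6, vertical ticks for the limma estimate over both). The Hox cluster list lies furthest left at -0.47, and the pluripotency list lies at -0.41 in pair 4 and 0.02 in pair 6.

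The lists of FGF signalling were not called. FGF ligands and receptors had a median log2 change of 0.05 over 7 genes with 1 of 7 below 0 (camera adjusted p = 0.218). FGF-ERK responsive genes and feedback inhibitors had -0.03 over 25 genes with 14 below 0 (camera adjusted p = 0.714), and the RAS, ERK and p38 kinase cascade had 0.05 over 31 genes with 6 below 0 (camera adjusted p = 0.218). Before centring, the medians of the FGF ligand and kinase cascade lists were -0.08 and -0.09. Subunits of the Gcn5-containing complexes SAGA and ATAC had a mean log2 change of 0.01 over 32 genes, with 17 below 0 (camera adjusted p = 0.901). Their largest changes were at Taf6l (0.25 ± 0.08, SE), Taf5l (-0.24 ± 0.14), Usp22 (0.20 ± 0.25) and Atxn7 (0.17 ± 0.09). Other histone acetyltransferases and deacetylases had a median of 0.01 over 18 genes (camera adjusted p = 0.614), and p53 targets and apoptosis genes -0.01 over 27 (camera adjusted p = 0.901). The remaining tested lists, which were epiblast, primitive streak and mesoderm, neuroectoderm, Wnt, TGF-beta, Nodal and BMP, and housekeeping genes, had medians from -0.06 (neuroectoderm) to 0.18 (primitive streak and mesoderm) and camera adjusted p from 0.218 to 0.901. The primitive streak and mesoderm value came from 5 genes, and with regions in at least 4 lists and a pseudocount the list was called narrower over 23 genes (median -0.33, camera adjusted p = 0.0464, and adjusted p = 0.531 with an estimated correlation). With the pseudocount alone it had a median of 0.13 over 5 genes (camera adjusted p = 0.608). The Wnt list had a median of 0.04 and a mean of -0.02. Adjusted over the list alone, Cdh2 of the epiblast list (-0.38 ± 0.10, SE) and Sfrp1 and Nkd1 of the Wnt list (-0.63 ± 0.15 and -0.31 ± 0.09) passed limma's test with p of 0.0393, 0.0312 and 0.0430, and over all regions none did.

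The lists were also compared by the number of members with a peak at an end. No list differed between genotypes after adjustment over 22 lists (exact permutation adjusted p = 1.0 for each). The design left little room for a call, since 1 list at the smallest exact p of 0.0286 would have an adjusted p of 0.629, and 13 lists would have to reach it to pass. Pluripotency genes had a peak at 70.8 ± 20.8% of 30 members in null and 80.8 ± 15.96% in fx/fx libraries (SD, n = 4 each), with 11 members marked in fewer null libraries and 0 in more. Prdm14, a regulator of naive pluripotency, was marked in 3 fx/fx and 1 null libraries, and Dppa4 in 3 and 2. Primitive streak and mesoderm genes were marked at 44.3 ± 15.6% in null and 57.1 ± 17.8% in fx/fx libraries (SD, n = 4 each), and Evx1 in 0 null and 2 fx/fx libraries. Neuroectoderm genes were marked at 57.1 ± 17.9% and 67.9 ± 13.1% (SD, n = 4 each), with Ncam1 and Pou3f2 marked in 3 fx/fx and 0 null libraries and Msi1 in 0 and 2. Endoderm genes were marked at 39.8 ± 18.5% and 49.1 ± 13.3%, and epiblast genes at 79.2 ± 18.9% and 90.3 ± 8.33% (SD, n = 4 each). Most of these differences lay in pair 4. For epiblast genes, null minus fx/fx was -22.2 points in pair 4 and 0.0 in pair 6. The values were -14.8 and -3.70 for endoderm, -17.1 and -4.29 for neuroectoderm, and -15.0 and -5.0 for pluripotency genes. Only primitive streak and mesoderm genes were close in both pairs, at -14.3 and -11.4. Sall2 and Sox3 of the epiblast list were marked in 4 fx/fx and 2 null libraries, and neither gene was marked in a null library of pair 4.

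FGF ligands and receptors were marked at 50.0 ± 11.8% of 29 genes in null and 57.8 ± 11.4% in fx/fx libraries (SD, n = 4 each). The ligand genes Fgf10 and Fgf15 were marked in 3 and 4 fx/fx libraries and in 1 and 2 null libraries, Fgf22 in 2 and 0, and the receptor gene Fgfr4 in 3 and 1. Myc targets were marked at 95.7 ± 2.34% of 64 genes in null and 98.0 ± 0.781% in fx/fx libraries (SD, n = 4 each), and Ccnd2, a D-type cyclin gene, in 0 null and 3 fx/fx libraries. SAGA and ATAC genes were marked at 97.7 ± 1.56% in both genotypes, and ribosomal protein genes at 100% in all 8 libraries. Adult tissue genes chosen beforehand as silent in embryoid bodies were marked at 12.9 ± 1.65% of 35 genes in both genotypes (SD, n = 4 each), with 4 of 35 marked in all 8 libraries.

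No region's genotype effect on width differed between the isolate pairs by limma's interaction term, with 677 regions at an unadjusted p under 0.05. With regions in at least 4 lists and a pseudocount, 247 regions differed. With the pseudocount alone, over regions in all 8 lists, 0 did. The 247 thus came with the addition of regions absent from some lists, where a missing peak enters as a width.

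Shares of peaks per chromosome were compared within isolate pairs. Chromosome 11 held 11.6% of peaks in 4_C2 and 10.1% in 4_1 libraries, and 8.82% in 6_C4 and 8.61% in 6_1 libraries (means of 2 replicates). The X chromosome held 1.87% in 4_C2 and 2.19% in 4_1 libraries, a log2 ratio of -0.23. By library it held 2.12% and 1.61% in replicates 1 and 2 of 4_C2, and 2.22% and 2.16% in those of 4_1. Its shares in 6_C4 and 6_1 libraries were 2.00% and 2.16%, a log2 ratio of -0.11. With 2 libraries per clone an exact test within a pair cannot pass the threshold.

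**Figure D4:**
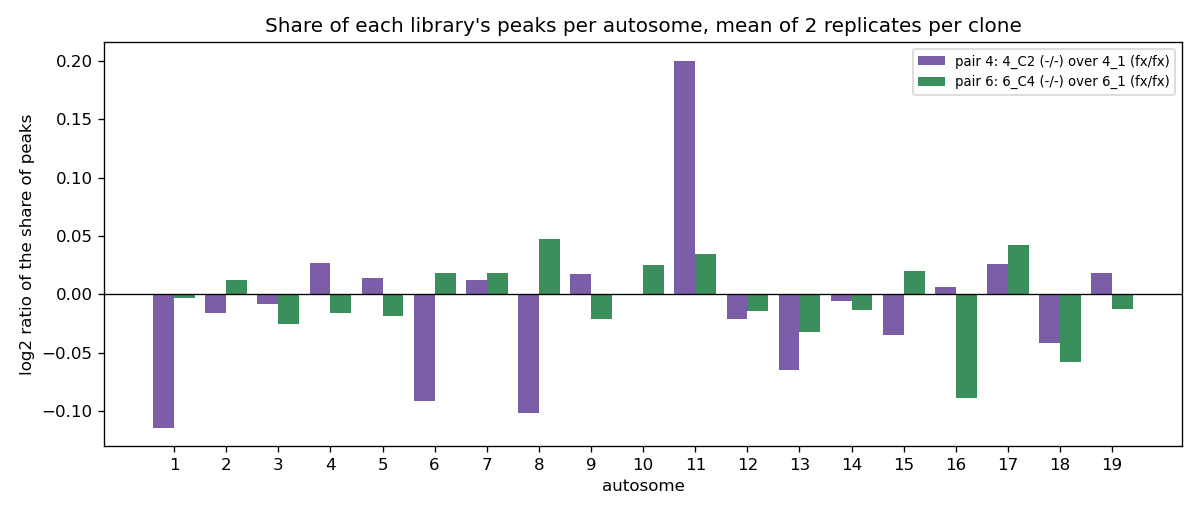
Log2 ratio of each autosome's share of peaks, null over fx/fx, in pair 4 and pair 6 (bars, means of 2 replicates per clone). Chromosome 11 stands highest in pair 4, at 0.20, and the highest of the other autosomes in that pair is at 0.03.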

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

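Across 44 measures and 88 groups of 4 libraries of one genotype, a library stood apart from the other 3 of its group 15 times by Dixon's test, and these came from 5 libraries. Chance meets the test in about 1 in 20 groups of continuous values. In 11 of the 15 the other 3 libraries held tied counts, where any difference passes, so that rate does not apply to them. Of the null libraries, replicate 2 of 4_C2 had fewer members with a peak than the other 3 for FGF-ERK responsive genes and feedback inhibitors (25 against 28 in each), for the RAS, ERK and p38 kinase cascade (33 against 35), for Myc targets (59 against 62), for other histone acetyltransferases and deacetylases (18 against 19) and for housekeeping genes (18 against 19). It also had the lowest median centred log2 width at FGF-ERK responsive genes, 0.61 against 0.74 to 0.76. Replicate 2 of 4_C2 is the shortest list, with 12041 peaks.

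Of the fx/fx libraries, replicate 2 of 4_1 had fewer epiblast genes with a peak (14 against 17), fewer Myc targets (62 against 63), fewer other histone acetyltransferases and deacetylases (19 against 20) and fewer TGF-beta, Nodal and BMP signalling genes (25 against 30 or 31). Replicate 2 of 6_1 had the highest median peak width, 2056 bp against 1809 to 1847 bp, more FGF-ERK responsive genes with a peak (29 against 28) and more SAGA and ATAC genes (32 against 31). Among null libraries, replicate 1 of 6_C4 had 32 SAGA and ATAC genes with a peak against 31, and replicate 1 of 4_C2 had a median centred log2 width of 0.21 at the Wnt list against 0.11 to 0.12.

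Library medians of the RAS, ERK and p38 kinase cascade list lay in opposite order in the isolate pairs. The median centred log2 width over its members was higher in both null than in both fx/fx libraries of pair 4, by 0.11, and lower in pair 6, by a change of -0.02. The median of the members' own changes was above 0 in both, at 0.07 in pair 4 and 0.05 in pair 6. The difference between the pairs was not tested for this list.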

How the results depend on the processing

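Of 119 results of alternatives with all libraries, 100 kept direction and side of the threshold, or stayed within 1.5 times for a count. Leaving out a library, 120 of 176 did. Alternatives by peak score (a stricter score and equal-length lists by score) were not run for lack of scores. Chosen after seeing the data were the settings with the widest peaks, peaks of at least 1000 bp, no chromosomes 8 and 11, genes with windows of their own, the pseudocount fit of the difference between pairs, a pseudocount alone, and an estimated correlation with a pseudocount and regions in at least 4 lists. The cause was not tested for the changes below, except that the pseudocount was also used alone. Lists called narrower numbered 2 with uncentred widths and 0 with an estimated correlation, over regions in all or in at least 4 lists. With a pseudocount alone they numbered 3. With regions in at least 4 lists and a pseudocount, 16 regions were narrower, 1 wider and 247 differed between the pairs. With the pseudocount alone each of these counts was 0. With 50% cover, 2 regions were present in null libraries alone and the overlap of gained regions was 1.67 times that expected (Fisher's exact p = 0.337). Equal-length lists by width, a cut that drops more narrow peaks from longer lists, gave a median width difference of -217.8 bp. Covered length differed by -3.06 Mb (exact permutation p = 0.343 for each). The gene-end share changed by -0.336 points, with 3 regions and 1 gene in null libraries alone and 2 narrower lists. The overlap of lost regions was 1.85 (Fisher's exact p = 0.0409). Peaks of at least 1000 bp gave a median width difference of -112.8 bp (exact permutation p = 0.0286), 2 regions and 1 gene in null libraries alone, and an overlap of gained regions of 2.45. Without chromosomes 8 and 11 the median width difference was -124.0 bp (exact permutation p = 0.0286). Genes with windows of their own gave a gene-end share difference of -0.0195 points.

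Leaving out each library in turn, with plain means or averaged within pairs, gave ranges of -2258 to 277 for the difference in peak number, -7.95 to -1.26 Mb for covered length, -184.5 to -61.0 bp for median width and -2.05 to 4.11 points for the gene-end share. The plain difference in peak number turned without replicate 2 of 4_C2 (277) or replicate 1 of 6_1 (258), and that in gene-end share without these (-2.05 and -2.03) or without replicate 2 of 6_1 (-0.492). Leaving out 1 library unbalances the pairs. Averaged within pairs, a setting chosen after seeing the data, peak number kept its direction without any one library (-1750 to -296.5), and the gene-end share turned without replicate 1 of 4_1 (-0.143), replicate 2 of 4_C2 (-0.653) or replicate 1 of 6_1 (-0.124). Counts ran from 18 to 63 regions and 10 to 38 genes in fx/fx libraries alone, and from 1 to 21 regions and 0 to 6 genes in null libraries alone. With 1 library fewer these counts ask less of each region. The largest, 63 and 38, came without replicate 1 of 6_C4, and 21 and 6 without replicate 2 of 4_C2. Overlap ratios ran from 0.387 to 1.97 for lost regions. Past the threshold, they lay below that expected without replicate 1 of 4_C2 or either of 6_1. They lay above it without replicate 1 of 4_1 or either of 6_C4. For gained regions the ratios ran from 0.104 to 2.21, past the threshold at 0.104 (without replicate 2 of 6_C4) and 1.58 (without replicate 2 of 4_C2). For lost genes, with settings chosen after seeing the data, the ratio ran from 1.35 to 4.64, past the threshold except without replicate 1 of 4_C2 (1.35) or replicate 2 of 6_1 (1.65). Narrower regions and regions differing between pairs ran from 0 to 1, and narrower lists from 1 (without replicate 2 of 4_1) to 4.

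With a replicate block over the numbers shared by the clones of a pair, the exact p was 0.125 for peak number, covered length and median width and 0.250 for the gene-end share, where 0.125 is the smallest possible, and limma and camera again called 0 regions and 4 lists. Deviations of same-numbered libraries correlated at 0.109 in pair 4 and 0.0624 in pair 6, so the numbers were not taken to pair the libraries. Permutation within isolate pairs gave exact p of 0.333, 0.111, 0.111 and 0.667 for the same measures in order, where 0.0556 is the smallest possible. Neither exact p could pass, so these results had to stay among the 100. The unknown depth limits every result here, because a missing peak can be a weak one.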

Other observations

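Markers of other cell types were also compared by genes with an end peak. Blood and endothelium genes were marked at 30.0 ± 10.1% of 25 in null and 35 ± 11.02% in fx/fx libraries, trophoblast genes at 31.8 ± 8.30% and 31.8 ± 14.4% of 22, fibroblast and feeder cell genes at 31.8 ± 11.7% and 36.4 ± 3.71% of 22, and germ cell genes at 28.1 ± 8.07% and 26.6 ± 9.38% of 16 (SD, n = 4 each, exact permutation adjusted p = 1.0 for each). Gata2, a regulator of blood stem cells, was marked in 4 fx/fx and 1 null libraries, and Tagln, a smooth muscle actin-binding protein gene, in 0 and 3. Among other lists, Wnt genes were marked at 65.3 ± 8.33% and 67.4 ± 11.9% of 36, TGF-beta, Nodal and BMP genes at 77.9 ± 13.04% and 85.3 ± 7.96% of 34, and Hox genes at 31.4 ± 10.3% and 40.4 ± 4.85% of 39 (SD, n = 4 each). In pairs 4 and 6, null minus fx/fx was -13.2 and -1.47 points for the TGF-beta list and -14.1 and -3.85 for Hox genes. Blood and endothelium genes went the other way, with -2.0 and -8.0, as did Wnt genes, with -4.17 in pair 6. Lefty1, a target and antagonist of Nodal signalling, was marked in 4 fx/fx and 2 null libraries.

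The isolate pairs differed more than the genotypes in the number of regions that separated them. Regions present in all 4 libraries of pair 6 and none of pair 4 numbered 741, against 10 the other way round, and genes numbered 137 against 5. The 137 genes included 3 of 28 pluripotency genes against 0.282 expected, namely Dppa3, Dppa5a and Dnmt3l (Fisher's exact p = 0.00271, adjusted p = 0.0597 over 22 lists), a list singled out after its value was seen. Pluripotency genes were marked at 90.8 ± 5.00% in pair 6 and 60.8 ± 11.3% in pair 4 libraries (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.126). All protein-coding genes were also marked more in pair 6, at 57.5 ± 1.12% against 52.1 ± 3.45% (SD, n = 4 each, exact permutation p = 0.0286).

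The tests of splits for regions and for widths, and of the Kat2a edge, were chosen after the results were seen. Chance cannot be excluded for the 17 regions present in all fx/fx and no null libraries, since 15 of 35 splits of the libraries into 4 and 4 gave at least as many and the highest other gave 741, nor for the 10 genes, where 9 of 35 did and the highest other gave 137. The split by isolate pair gave those highest values, which points to a structure of the samples. Among the 18 splits that divide both pairs evenly, 5 gave at least 17 regions, with the highest other at 28, and the real split alone gave 10 genes, with the highest other at 9. The split by replicate number gave 25 regions. For widths the splits say nothing about chance, since with 0 regions called each of the 34 splits that could be fitted gives as many. The highest other gave 1.

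For the narrower lists, 1 of the 34 splits gave as many as 4 called lists, the real one, and the highest other gave 3. Most of the other splits also called at least 1 list, and every list they called was one of these 4. The split with 3 called pluripotency, Myc targets and ribosomal proteins. Camera thus called these lists under groupings unrelated to genotype, so a call alone does not tie a list to Gcn5. Among the 18 splits that divide both pairs evenly the real one alone gave 4, with the highest other at 2, and 18 splits are too few for a share under 0.05. A tendency of wide regions to narrow more was argued against by random lists matched on mean width. Medians lay at percentile 0.04 for pluripotency, 1.51 for Myc targets, 0.0 for Hox clusters and 0.09 for ribosomal proteins among 10000 such lists. Correlated behaviour of the members stays open, since with an estimated correlation 0 lists were called, and so does a dependence on single libraries. Of the 4 lists, ribosomal proteins had been fixed beforehand as a control. A lower acetylation of the genes of these lists upon Gcn5 loss is a hypothesis that widths of called peaks cannot settle.

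Chromosome 11, which carries Kat2a, held a larger share of peaks in 4_C2 libraries than in 4_1 libraries, 11.6% against 10.1%, a log2 ratio of 0.20 where the highest other autosome had 0.03. The X chromosome also differed, with log2 ratios of -0.23 in pair 4 and -0.11 in pair 6. The pair 4 value came mostly from replicate 2 of 4_C2, the shortest list. In lists of the 12041 widest peaks it was -0.127, close to the -0.129 of chromosome 8. In pair 6 the shares of chromosome 11 were 8.82% in 6_C4 and 8.61% in 6_1. The fx/fx clone 4_1 thus also lay above 6_1, so a higher share was not particular to the null clone. By pair, chromosome 11 held 10.9% in pair 4 and 8.71% in pair 6, and chromosome 8 held 5.50% and 6.35%. Each had an unadjusted exact permutation p of 0.0286, which other chromosomes also reached. Shorter lists favouring gene-rich chromosomes were argued against by lists of 12041 widest peaks each, which gave 0.20 with the highest other autosome at 0.04, and a few regions by the ratio of 0.19 left without the 3 bins of largest excess. The share was higher in 4_C2 in 12 of 13 bins of 10 Mb (92.3%), which is what extra copies of chromosome 11 in these cells may give. That hypothesis was noticed in these data, copy number was not measured here, and a change of acetylation along the chromosome stays open.

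At Kat2a the peak started inside the gene, between 100710715 and 100711441 in the 4 fx/fx libraries and between 100711559 and 100711609 in the 4 null libraries (difference 354.5 bp, exact permutation p = 0.0286, the smallest possible). Replicate 1 of 6_1 gave the lowest start, and without it the difference was 181.8 bp. Without other libraries it ran up to 423.8 bp, with exact permutation p up to 0.0857. Of 20342 peak edges of regions in all lists, 513 (2.52%) lay further inside in every null than in every fx/fx library, and 19 (0.0934%) also with null edges within 50 bp of each other. That criterion was taken from the Kat2a edges themselves, so chance variation of edges stays open. A candidate explanation is that the deleted segment begins near this point, so that null cells give no reads beyond it. The limits of the deletion are not given in the sources used here, and narrower acetylation at this gene was not excluded.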
